A study of Homo sapiens with 12 samples.

How the data were processed

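RNA of Tet21N cells was measured on 12 Illumina bead arrays, 3 for each combination of siRNA (MondoA or non-specific) and Myc state (no doxycycline, Myc on, or 1 microgram/ml for 3 days, Myc off). Per the labels' protocols, RNA was purified on RNeasy Plus columns and biotinylated cRNA was made with the Ambion MessageAmp kit. Groups and replicate numbers came from the labels. The labels name no slide or scan date, so no batch could be tested.

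The authors deposited bead-summarized probe intensities per array, on a linear scale and, by their values, neither background-subtracted nor normalized; the scanner software is not given in the sources used here. The deposited detection score of each probe and array was found from the values to be 1 minus the detection p-value. The authors also deposited log2 values, which were found to equal the log2 of the quantile-normalized intensities without background correction (largest difference 5.3e-14). The deposited log2 column of each of the 12 arrays correlated best with its own signals (lowest own r 0.999, highest other r 0.994), and the column medians were 7.0542 to 7.0555. Per the submitters' processing notes lumi was used, with its version and role not given in the sources used here.

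The table held 47323 probes, 10 of them without values. Probes were named through the platform annotation, updated by gene identifier to RefSeq symbols. Of the probes with values 30108 had 1 gene symbol, 8 had several and 17197 had none; 30069 matched the RefSeq table and 0 symbols changed. Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16. Probes with a detection p below 0.05 on at least 3 of the 12 arrays were kept (22188, of which 16385 had 1 gene symbol). For the 3288 genes with more than 1 such probe, the probe with the highest mean over the 12 arrays was used, which left 12178 genes. A gene not detected on any array of a group has only a bound there. Its fold is then given as "at least", from the brighter group's mean against the mean, per array of the dimmer group, of the higher of the lowest detected signal and the probe's own signal, on normalized log2 values.

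A cell means model over all 12 arrays was fitted with limma (lmFit and eBayes, 8 residual and 4.552 prior degrees of freedom), so that all groups shared 1 estimate of the spread. The comparisons were siMondoA against siControl with Myc on and with Myc off, Myc on against Myc off with siControl and with siMondoA, and the interaction, which is the knockdown change with Myc on minus that with Myc off. All p-values of genes are limma's, Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. The median SE of a log2 change was 0.15, and the number of arrays limits the precision. Gene lists were tested with limma's camera (preset correlation 0.01, adjusted over the 23 lists within a comparison), and again with the correlation estimated and with fry. Ranges over a list's alternatives are those of camera with the preset correlation. The fry test asks whether a list's genes move on balance in 1 direction and does not compare them with other genes.

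The 23 lists were the extended MYC network, MondoA and ChREBP targets, MYC-induced nucleolar genes, MYC-repressed genes, cholesterol synthesis, fatty acid synthesis, glycolysis, glutamine and amino acid transport and use, serine and one-carbon metabolism, nucleotide synthesis, oxidative phosphorylation, the ATF4 and amino acid stress response, p53 targets, the BCL2 family, DNA replication, mitosis, hypoxia, interferon response, adrenergic and mesenchymal neuroblastoma markers, markers of blood, endothelium and epithelium, extracellular matrix, and lysosome and autophagy. Some genes are in more than 1 list. The groups, models, lists and the rule for named genes were fixed before the data were examined, and so were the alternatives, except median scaling of the gene lists and all alternatives for the gene families. By that rule MLXIP, MYCN and MYC were named in every group; in each pairwise comparison the 8 highest and 8 lowest log2 changes among called genes with a non-provisional symbol whose 3 arrays of one group all lay above or below the other 3; for the interaction the 6 highest and 6 lowest; up to 4 members per list with the largest change, plus members a list is described by; and TXNIP and ARRDC4 always.

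The fit and the calling of genes were tested on simulated normalized values with 200 of 12178 genes changed and independent noise for each gene. The background correction, normalization, probe filter and choice of probe were not part of that test. In the data 8.7% to 43.8% of genes were called, so the percentages found in the simulation need not carry over. A log2 change of 1 was found for 74%, 85%, 77% and 80% of changed genes in the 4 pairwise comparisons in the order given and for 48% in the interaction. A log2 change of 0.5 was found for 24%, 20%, 28%, 30% and 7%, with 7, 6, 4, 4 and 0 false calls and 0 with the wrong sign. The alternatives tried were the authors' values, no background correction, another offset, median scaling, other filters on dim probes, the mean of a gene's probes, a replicate block, only the groups compared, array weights, a fold minimum, and each array left out in turn. The 5803 detected probes without a single symbol were tested in a fit of their own and are given as counts only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.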

Results

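Transcript levels were measured on 12 Illumina bead arrays of RNA from Tet21N cells, a human neuroblastoma line with an N-Myc transgene that doxycycline switches off. Cells received an siRNA against MondoA, the nutrient-responsive transcription factor encoded by MLXIP, or a non-specific siRNA (siControl). They were kept for 3 days without doxycycline (Myc on) or with 1 microgram/ml of it (Myc off), which gave 4 groups of 3 arrays. By its title, the study asked whether deregulated Myc depends on MondoA for its metabolic programme. Between 18521 and 20726 probes per array were detected above background, 39.15% to 43.81% of the 47313 with values. The median signal per array was 116.8 to 143.2, against a mean background of 107.7 to 131.7. Arrays of 1 group correlated at r = 0.986 to 0.992 across the genes tested and arrays of different groups at 0.945 to 0.973. The first principal component (43.1% of the variance) separated the siRNAs and the next (27.3%) the Myc states. Every Myc-off array came from doxycycline-treated cells, so the drug and Myc cannot be told apart. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

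The genes manipulated in the design were examined first. The MLXIP probe was detected on 1 of the 12 arrays, and the MYCN probes on 0, so neither could check the labels. The only array with a detected MLXIP signal was in the siControl, Myc-on group. TXNIP, the thioredoxin-interacting protein and a direct MondoA target, was well above background on all arrays. Its mean log2 level was 11.31 ± 0.05 (SD, n = 3) with siControl and 7.96 ± 0.16 with siMondoA when Myc was on, and 11.09 ± 0.14 and 6.67 ± 0.10 when Myc was off. The ARRDC4 probes, for another direct target, were not above background on at least 3 arrays and ARRDC4 was not tested. The MYC transcript, which encodes c-Myc and not the N-Myc of the transgene, was at 6.15 ± 0.23 with siControl and 7.93 ± 0.18 with siMondoA when Myc was on. When Myc was off it was at 9.10 ± 0.05 and 8.93 ± 0.08. "Myc on" and "Myc off" are the labels' names and do not describe the MYC transcript, which was lower on the arrays labelled Myc on.

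**Figure D1:**
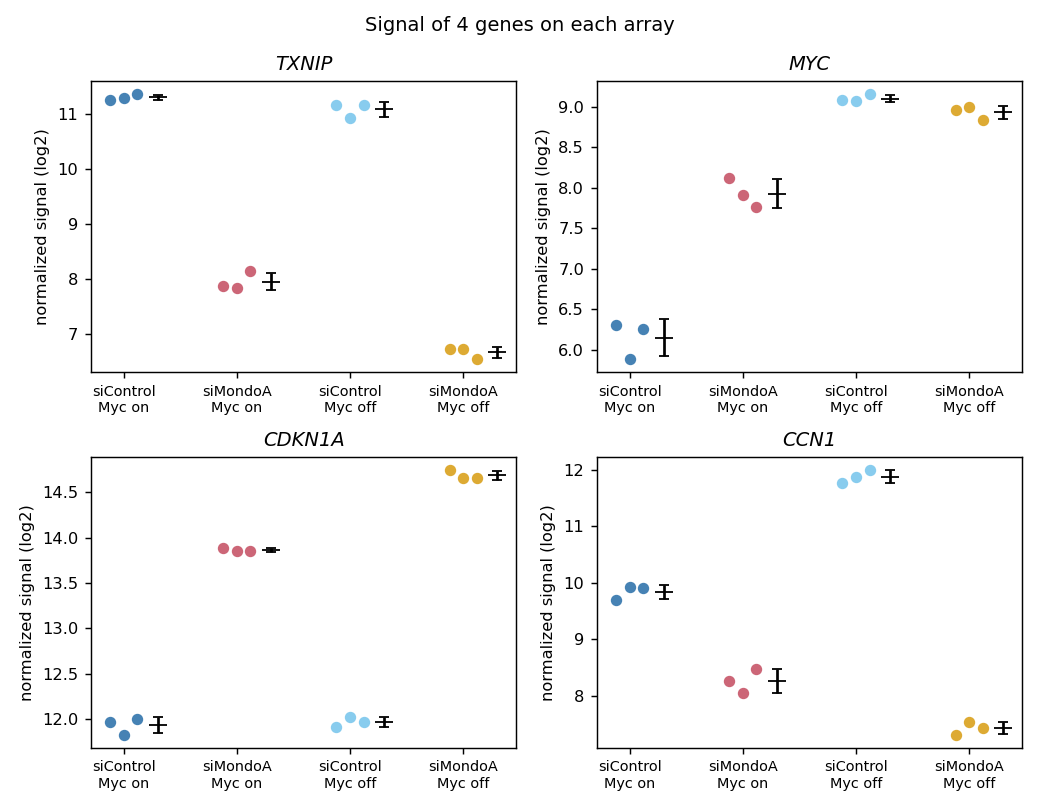
Normalized log2 signal of TXNIP, MYC, CDKN1A and CCN1 on each of the 12 arrays, with dots for arrays and bars for the mean ± SD of each group of 3. TXNIP lay between 11.09 and 11.31 on average with siControl and at 7.96 and 6.67 with siMondoA.

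With Myc on, the MondoA siRNA lowered TXNIP by 10.2-fold (log2 change -3.35 ± 0.12, SE, n = 3 per group, adjusted p = 8.6e-09). The genes that rose furthest were NTS, which encodes neurotensin, by 18.4-fold (4.20 ± 0.18), the matrix protease gene MMP3 by 16.4-fold (4.03 ± 0.17) and UTS2, which encodes urotensin, by 10.6-fold (3.40 ± 0.15). Histone genes followed, with H2AC18 at 9.03-fold, H2AJ at 8.82-fold and H4C8 at least 5.58-fold higher, H4C8 not being above background in siControl. NDP (7.67-fold) and the chemokine gene CXCL1 (7.09-fold) rose too, each detected on 2 of the 3 siControl arrays. Besides TXNIP, PKD1L1-AS1 fell by 2.51 on the log2 scale, MFAP4 by 5.64-fold, JUP, which encodes plakoglobin, by 4.42-fold and the interferon-inducible IFITM1 by 4.33-fold. RARRES2, TMEM119 and APOE were not above background with siMondoA and were at least 3.92-fold, 3.6-fold and 3.3-fold lower. MYC rose 3.43-fold (1.78 ± 0.13, adjusted p = 2e-06). Other detected probes moved less for JUP (-0.40 and -0.52, neither passing) and UTS2 (0.40, not passing, and 3.34).

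Of the gene lists, 5 of 23 passed camera in this comparison. Among p53 targets, 7 of 13 rose, ZMAT3 fell and 5 did not pass, with the same 7 and 1 adjusted over the list alone (median 0.42, adjusted p = 0.013). CDKN1A, the cell cycle inhibitor p21, rose by 1.93 ± 0.09 (another probe 1.30) and TP53I3 by 1.32 ± 0.13, another TP53I3 probe being at 0.47 without passing. In the cholesterol synthesis list 8 of 19 fell, 1 rose and 10 did not pass (9 and 1 adjusted over the list alone, median -0.36, adjusted p = 0.013), with INSIG1, the sterol-sensing regulator, at -1.28 ± 0.11. In the fatty acid list 3 of 13 fell and 10 did not pass (6 lower and 1 higher adjusted over the list alone, median -0.24, adjusted p = 0.026). These 3 were SREBF1, the lipogenic transcription factor (-1.83 ± 0.12, other probes -0.62 and -1.57), SCD, the stearoyl-CoA desaturase (-1.47 ± 0.12), and ACACA, the acetyl-CoA carboxylase (-0.72 ± 0.12). Of the extracellular matrix list 9 of 21 fell, 4 rose and 8 did not pass (10 and 4 adjusted over the list alone, median -0.23, adjusted p = 0.025). COL1A1, a collagen I chain, was at -1.71 ± 0.10 and CCN1, a matricellular protein gene, at -1.58 ± 0.13, while the protease MMP14 was at 1.26 ± 0.17. Of the MYC-induced nucleolar list 5 of 17 rose, 0 fell and 12 did not pass (7 higher adjusted over the list alone, median 0.22, adjusted p = 0.026), led by the ribosome biogenesis factors RRS1 (0.62 ± 0.11) and RRP12 (0.58 ± 0.11). None of these 5 calls held when the correlation was estimated: adjusted p = 0.14 with an estimated correlation for the first 4 lists named and 0.15 for the nucleolar list.

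In limma, 3026 of the 12178 genes tested (24.8%) passed the threshold with Myc on, 1504 higher and 1522 lower, and 354 of them changed at least 2-fold, 144 higher and 210 lower. The groups did not overlap for 40.4% of genes, where chance gives 10%. Higher genes made up 49.7% of the calls, and 79.1% under median scaling in place of quantile normalization, which put the median of all genes at 0.19. That scaling ended the calls of the cholesterol list (adjusted p = 0.076, range 0.0021 to 0.076 over its alternatives) and of the fatty acid list (0.15, range 0.0067 to 0.15, median 0.01 and so turned in sign). Without siMondoA Myc-on replicate 1 the fatty acid and nucleolar lists had adjusted p = 0.075 and 0.073, and without siControl Myc-on replicate 1 the nucleolar list had 0.056, the nucleolar range being 0.0039 to 0.073.

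With Myc off, the same siRNA lowered TXNIP by 21.4-fold (-4.42 ± 0.12, SE, n = 3 per group, adjusted p = 2.9e-10) and CCN1 by 21.9-fold (-4.45 ± 0.13, adjusted p = 5e-10). The other genes that fell furthest were COL12A1, a fibril-associated collagen (15.2-fold), PKD1L1-AS1 (14-fold), the succinate receptor SUCNR1 (9.24-fold), TMEM30A (8.89-fold), TAPBP, which encodes tapasin of the peptide-loading complex (8.83-fold), and the complement gene CFB (8.29-fold). NTS rose 16-fold (4.0 ± 0.18), the histone genes H4C8 and H4C12 by 9.97-fold and 6.56-fold, PGF, a placental growth factor gene, by 8.17-fold, MMP3 by 7.35-fold, CDKN1A by 6.59-fold (2.72 ± 0.09), H2AJ by 6.35-fold and CHST2 by 5.95-fold. CHST2 was detected on 2 of the 3 siControl arrays. Other detected TAPBP probes were at -0.23, which did not pass, and -0.70, and another CDKN1A probe was at 3.40. MYC did not pass (-0.17 ± 0.13, adjusted p = 0.32), and its other probe was at 0.16.

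Among the lists, 5 of 23 passed with Myc off. Of the mitosis list 15 of 20 fell, 0 rose and 5 did not pass (16 lower adjusted over the list alone, median -0.56, adjusted p = 2.9e-05), among them the kinesin KIF20A (-1.49 ± 0.13), the topoisomerase TOP2A (-1.41 ± 0.14) and the proliferation marker MKI67 (-1.28 ± 0.17). Of p53 targets 10 of 13 rose, ZMAT3 fell and 2 did not pass (10 and 1 adjusted over the list alone, median 1.03, adjusted p = 6.5e-05), with SESN1 at 1.70 ± 0.11 and GDF15 at 1.49 ± 0.14. Of the extracellular matrix list 14 of 21 fell, 3 rose and 4 did not pass, also adjusted over the list alone (median -0.61, adjusted p = 0.00044). CCN2, a connective tissue growth factor gene, was at -3.00 ± 0.11 and COL1A1 at -2.05 ± 0.10, while LOX, the collagen cross-linking oxidase, was at 0.89 ± 0.14. These 3 calls held with an estimated correlation (adjusted p = 0.015, 0.015 and 0.043). Of the oxidative phosphorylation list 25 of 50 rose, 3 fell and 22 did not pass (26 and 3 adjusted over the list alone, median 0.29, adjusted p = 0.0022, but adjusted p = 0.099 with an estimated correlation). The complex III subunit UQCRB was at 1.19 ± 0.12 and SDHD of complex II at 1.18 ± 0.16, whereas NDUFA2 of complex I was at -1.24 ± 0.10. Of the ATF4 and amino acid stress list 10 of 17 fell, 2 rose and 5 did not pass (11 and 2 adjusted over the list alone, median -0.35, adjusted p = 0.013, but adjusted p = 0.07 with an estimated correlation). Of the transsulfuration enzymes CBS was at -1.49 ± 0.12 and CTH at -1.25 ± 0.19, and SESN2 was at 1.99 ± 0.23. Of the DNA replication list 11 of 19 fell, 3 rose and 5 did not pass, also adjusted over the list alone, and the list itself did not pass (median -0.32, adjusted p = 0.052, range 0.013 to 0.26 over its alternatives).

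In limma, 5333 genes (43.8%) passed with Myc off, 2659 higher and 2674 lower, and 1095 changed at least 2-fold, 433 higher and 662 lower. The groups did not overlap for 52.3% of genes, where chance gives 10%. Higher genes made up 49.9% of these calls and 37.2% under median scaling.

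The knockdown calls with Myc on and with Myc off share no arrays. Both comparisons called 1029 genes higher, where independent lists would share 328, and 1202 lower, where they would share 334. Only 62 genes were called in opposite directions, where 663 would be by the same reckoning. TXNIP, NTS, MMP3, PKD1L1-AS1, H2AJ and H4C8 were among the 8 furthest changed per direction in both states. Across genes, which are not independent replicates, the log2 changes correlated at Pearson r = 0.694.

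**Figure D2:**
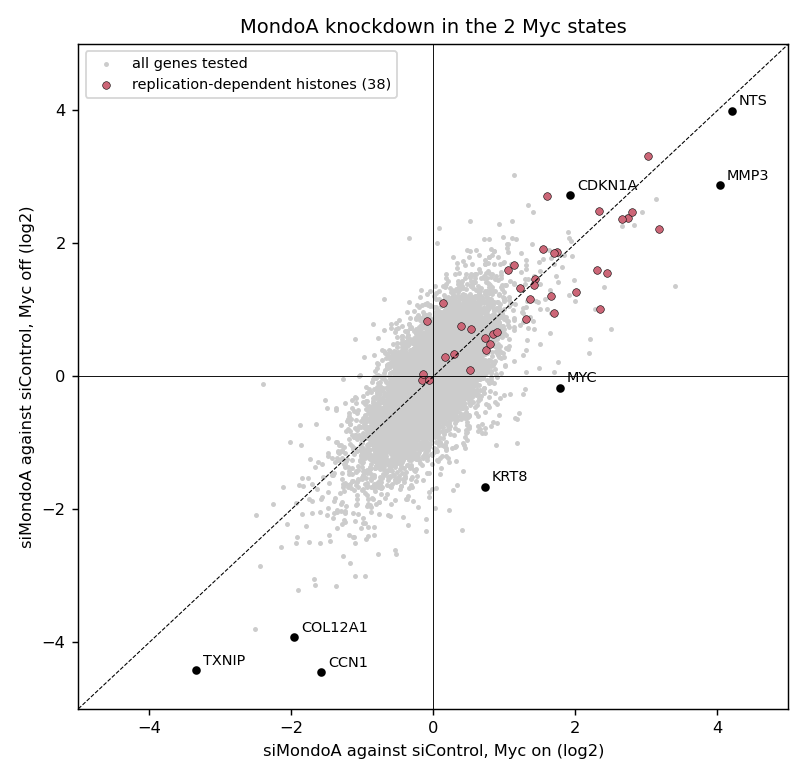
Log2 change of every tested gene with the MondoA siRNA when Myc was on (horizontal axis) and off (vertical axis), each dot a gene, with 38 replication-dependent histone genes in red and a dashed line where both changes are equal. TXNIP lies at -3.35 and -4.42, NTS at 4.20 and 4.0, and CCN1 at -1.58 and -4.45; the histones, picked out after the data were seen, lie mostly in the upper right, also under median scaling.

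In siControl cells, Myc on against Myc off raised VCAN, which encodes the proteoglycan versican, by 5.91-fold (2.56 ± 0.14, SE, n = 3 per group, adjusted p = 2.2e-07), the fatty acid binding protein gene FABP5 by 5.42-fold (2.44 ± 0.16) and the corepressor gene RCOR2 by 5.09-fold (2.35 ± 0.16). CNTNAP2 (4.28-fold), RBPMS2 (3.32-fold), and the transporter genes SLCO4A1 (3.15-fold) and SLC7A2 (3.11-fold) rose as well, and TMEM119, not above background with Myc off, was at least 3.75-fold higher. The genes that fell furthest were PSG4 (9.08-fold), MYC itself (7.74-fold, -2.95 ± 0.13, adjusted p = 3.1e-08), CRISPLD2 (7.56-fold), the chemokine scavenger receptor gene ACKR3 (7.29-fold), the carboxypeptidase gene CPA4 (7.14-fold), MMP3 (6.17-fold), FILIP1L (5.91-fold) and the adrenergic receptor gene ADRA1B (5.89-fold). Other detected probes were at -1.58 and -1.48 for PSG4, against -3.18, and at 1.79 for FABP5. TXNIP did not pass (0.22 ± 0.12, adjusted p = 0.18).

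Here 12 of 23 lists passed. Nucleotide synthesis had 15 of 19 members higher, 0 lower and 4 not passing (16 higher adjusted over the list alone, median 0.52, adjusted p = 2.7e-08), with PPAT, the first enzyme of purine synthesis, at 1.09 ± 0.11 and the pyrimidine enzyme CAD at 1.01 ± 0.13. In the DNA replication list 15 of 19 rose, 0 fell and 4 did not pass, also adjusted over the list alone (median 0.45, adjusted p = 2.7e-08), with the licensing factor CDT1 at 0.98 ± 0.14. In the nucleolar list 12 of 17 rose, 0 fell and 5 did not pass (13 higher adjusted over the list alone, median 0.62, adjusted p = 6e-07), with FBL, the rRNA methyltransferase fibrillarin, at 0.96 ± 0.12. In the mitosis list 11 of 20 rose, 0 fell and 9 did not pass (14 adjusted over the list alone, median 0.40, adjusted p = 6.3e-06), with CDK1 at 1.06 ± 0.17. Serine and one-carbon metabolism had 5 of 8 members higher, 0 lower and 3 not passing, also adjusted over the list alone (median 0.49, adjusted p = 1e-04), led by MTHFD2 (1.33 ± 0.12) and PSAT1 (1.06 ± 0.10). Glutamine and amino acid transport had 6 of 14 higher, 0 lower and 8 not passing, also adjusted over the list alone (median 0.20, adjusted p = 0.022, but adjusted p = 0.058 with an estimated correlation), with the leucine transporter SLC7A5 at 0.90 ± 0.10. Oxidative phosphorylation had 10 of 50 higher, 0 lower and 40 not passing (8 higher adjusted over the list alone, median 0.12, adjusted p = 0.018, but adjusted p = 0.13 with an estimated correlation), and without siControl Myc-off replicate 3 its adjusted p was 0.059 (range 0.0013 to 0.059).

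The lists that fell in siControl cells with Myc on were of matrix, lysosome, sterol, mesenchymal and interferon genes. Of the extracellular matrix list 17 of 21 fell, 0 rose and 4 did not pass (18 adjusted over the list alone, median -0.69, adjusted p = 3.3e-10), with CCN1 at -2.04 ± 0.13 and COL5A1 at -1.19 ± 0.10. Of the lysosome and autophagy list 14 of 16 fell, 0 rose and 2 did not pass (15 adjusted over the list alone, median -0.69, adjusted p = 2.7e-08), with the sialidase NEU1 at -1.31 ± 0.12 and the protease gene CTSD at -1.12 ± 0.17. Of the cholesterol list 11 of 19 fell, 0 rose and 8 did not pass (12 adjusted over the list alone, median -0.56, adjusted p = 2.5e-05), with LSS, the lanosterol synthase, at -1.31 ± 0.12 and its other probe at -0.66. Of the mesenchymal neuroblastoma markers 10 of 14 fell, 0 rose and 4 did not pass, also adjusted over the list alone (median -0.44, adjusted p = 3.6e-05), with SPARC at -1.79 ± 0.16 and the transcription factor SNAI2 at -1.35 ± 0.12. Of the interferon list 7 of 16 fell, 0 rose and 9 did not pass (8 adjusted over the list alone, median -0.35, adjusted p = 0.00016), with the transcription factors IRF7 at -1.81 ± 0.20 and IRF9 at -1.40 ± 0.13. Apart from the glutamine and oxidative phosphorylation lists, all calls of this comparison held with an estimated correlation. The MondoA and ChREBP target list did not pass (median 0.05, adjusted p = 0.33), while its member HK2, a hexokinase gene, rose by 1.49 ± 0.13, its other detected probe being at 0.32 and not passing.

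In limma, 3757 genes (30.9%) passed in siControl cells, 1774 higher and 1983 lower, and 472 changed at least 2-fold, 155 higher and 317 lower. The groups did not overlap for 45% of genes, where chance gives 10%. Higher genes made up 47.2% of the calls and 25.6% under median scaling, which put the median of all genes at -0.11.

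In siMondoA cells, Myc on against Myc off raised EEF1A2, a translation elongation factor gene, by 6.84-fold (2.78 ± 0.14, SE, n = 3 per group, adjusted p = 3.4e-07) and MCM10, a DNA replication factor gene, by 3.56-fold (1.83 ± 0.16). The SNORD56 probe, detected on 1 of the 3 Myc-off arrays, was 4.06-fold higher, the neurotensin receptor gene NTSR1 was at least 2.79-fold higher, and MIX23, UTS2, GLRX5 and CTXN1 rose 3.49-fold, 3.28-fold, 3.2-fold and 3.19-fold. The genes that fell furthest were SEMA5A (5.07-fold), the antigen-presenting HLA-B (4.87-fold), GPNMB (4.81-fold), INSIG1 (4.5-fold), HSD17B14 (4.39-fold, detected on 1 of 3 Myc-on arrays), GCNT3 (4.02-fold) and SLCO2B1 (3.96-fold), with the inflammatory caspase gene CASP1 at least 3.4-fold lower. TXNIP rose 2.44-fold (1.29 ± 0.12, adjusted p = 1.4e-05) and MYC fell 2.01-fold (-1.0 ± 0.13, adjusted p = 0.00015). Other detected probes of INSIG1 and UTS2, at -0.23 and 0.03, did not pass, and another SEMA5A probe was at -1.10 against -2.34.

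With siMondoA, 14 of 23 lists passed. All 20 mitosis genes rose, also adjusted over the list alone (median 1.01, adjusted p = 2.3e-15), with the kinase AURKB at 1.49 ± 0.13 and BUB1 at 1.34 ± 0.11. In the DNA replication list 16 of 19 rose, 0 fell and 3 did not pass, also adjusted over the list alone (median 0.84, adjusted p = 3.9e-12), with the helicase subunit MCM4 at 1.26 ± 0.15. In nucleotide synthesis 17 of 19 rose, 0 fell and 2 did not pass, also adjusted over the list alone (median 0.53, adjusted p = 5.6e-09), with RRM2 of ribonucleotide reductase at 1.37 ± 0.11. In the nucleolar list 14 of 17 rose, 0 fell and 3 did not pass, also adjusted over the list alone (median 0.59, adjusted p = 7.1e-09), with NOP56 at 1.40 ± 0.12. All 8 serine and one-carbon genes rose, also adjusted over the list alone (median 0.76, adjusted p = 2.3e-06), with PHGDH, the first enzyme of serine synthesis, at 0.80 ± 0.11. In the glutamine list 6 of 14 rose, GOT1 fell and 7 did not pass (7 and 1 adjusted over the list alone, median 0.41, adjusted p = 0.0058), with SLC7A5 at 1.40 ± 0.10. In the MondoA and ChREBP target list 3 of 6 rose, 0 fell and 3 did not pass, also adjusted over the list alone (median 0.36, adjusted p = 0.0082, but adjusted p = 0.12 with an estimated correlation); these were TXNIP, HK2 (0.94 ± 0.13, another probe 0.39 without passing) and the lactate dehydrogenase gene LDHA (0.40 ± 0.11).

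Lower with Myc on in siMondoA cells were 7 lists. In the interferon list 13 of 16 fell, 0 rose and 3 did not pass (14 adjusted over the list alone, median -0.72, adjusted p = 7.1e-09), with IFIT2 at -1.49 ± 0.15 and IRF7 at -1.52 ± 0.20. In the lysosome list 11 of 16 fell, 0 rose and 5 did not pass (13 adjusted over the list alone, median -0.76, adjusted p = 5.5e-08), with NEU1 at -1.57 ± 0.12. In the cholesterol list 13 of 19 fell, 0 rose and 6 did not pass, also adjusted over the list alone (median -0.73, adjusted p = 5.5e-08), with HMGCS1, the HMG-CoA synthase, at -1.79 ± 0.15. In the p53 target list 7 of 13 fell, 0 rose and 6 did not pass (10 adjusted over the list alone, median -0.52, adjusted p = 0.00021), with CDKN1A at -0.82 ± 0.09 and its other probe at -2.09. In the matrix list 9 of 21 fell, 2 rose and 10 did not pass, also adjusted over the list alone (median -0.29, adjusted p = 0.0025); COL3A1 was at -0.85 ± 0.13, and the pair that rose was CCN1 (0.83 ± 0.13) and CCN2 (0.41 ± 0.11). In the MYC-repressed list 4 of 9 fell, 0 rose and 5 did not pass, also adjusted over the list alone (median -0.33, adjusted p = 0.021, but adjusted p = 0.06 with an estimated correlation), with GADD45A at -0.66 ± 0.12. In the fatty acid list 5 of 13 fell, 0 rose and 8 did not pass (6 adjusted over the list alone, median -0.29, adjusted p = 0.033, but adjusted p = 0.069 with an estimated correlation), with SCD at -0.87 ± 0.12. The other 11 calls of this comparison held with an estimated correlation.

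In limma, 3655 genes (30%) passed in siMondoA cells, 1818 higher and 1837 lower, and 436 changed at least 2-fold, 220 higher and 216 lower. The groups did not overlap for 41.8% of genes, where chance gives 10%. Higher genes made up 49.7% of the calls and 76.2% under median scaling, which put the median of all genes at 0.13. The fatty acid call ended under that scaling (adjusted p = 0.076) and without siMondoA Myc-on replicate 1 (0.11, range 0.0096 to 0.11 over its alternatives), and the MYC-repressed call ended without siMondoA Myc-off replicate 2 (0.069, range 0.0097 to 0.069).

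The Myc-state calls with the 2 siRNAs also share no arrays. Both called 892 genes higher, where independent lists would share 265, and 924 lower, where they would share 299, while 132 were called in opposite directions, where 564 would be. CCN1 (-2.04 with siControl and 0.83 with siMondoA) and KRT8 (-1.06 and 1.32) were called in opposite directions. Across genes the log2 changes correlated at Pearson r = 0.539.

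**Figure D3:**
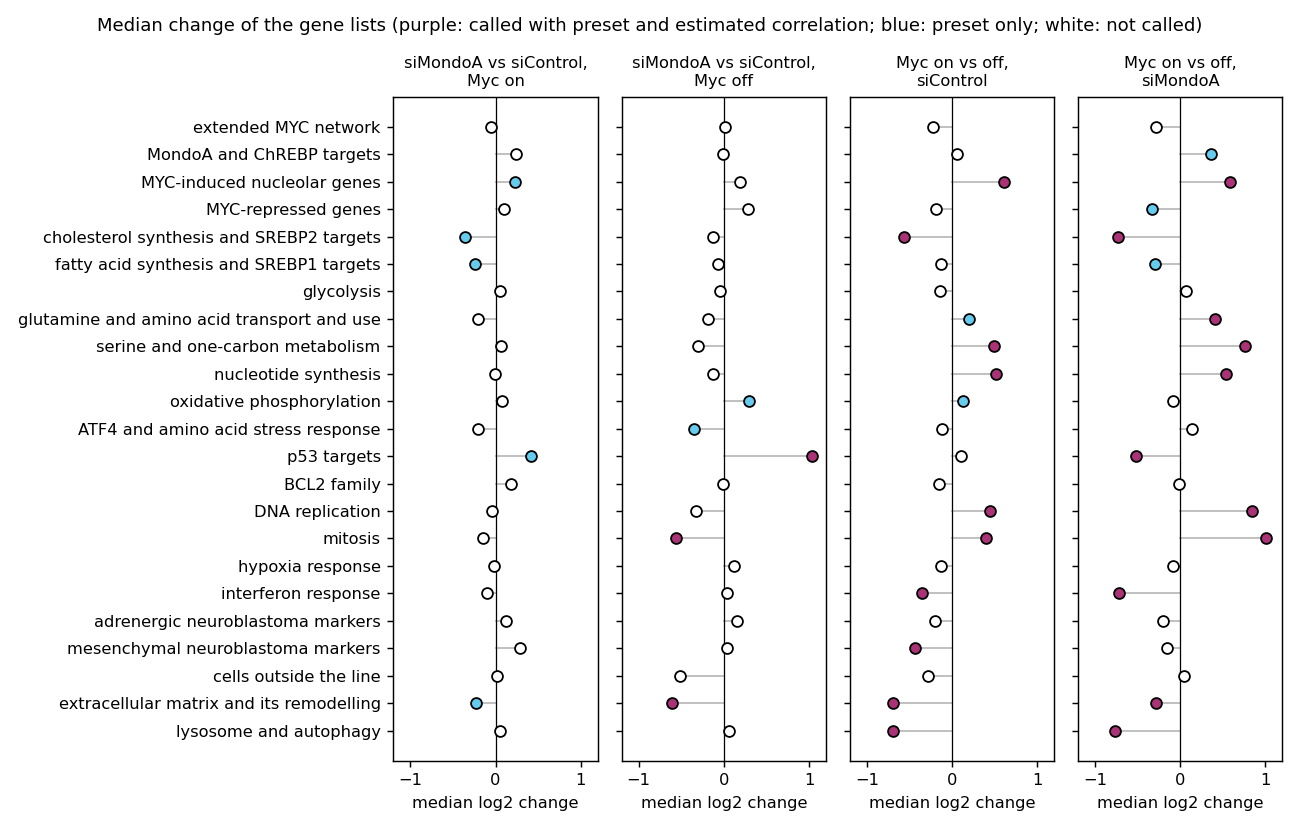
Median log2 change of the tested members of each of the 23 gene lists (1 line per list) in the 4 pairwise comparisons (1 panel each), with purple dots for lists passing camera with the preset and the estimated correlation, blue dots for those passing with the preset correlation only and white dots for the others. The mitosis list lies at -0.56 for the knockdown with Myc off and at 1.01 for Myc state with siMondoA; the fatty acid list of the first panel (-0.24) turns to 0.01 under median scaling.

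**Figure D4:**
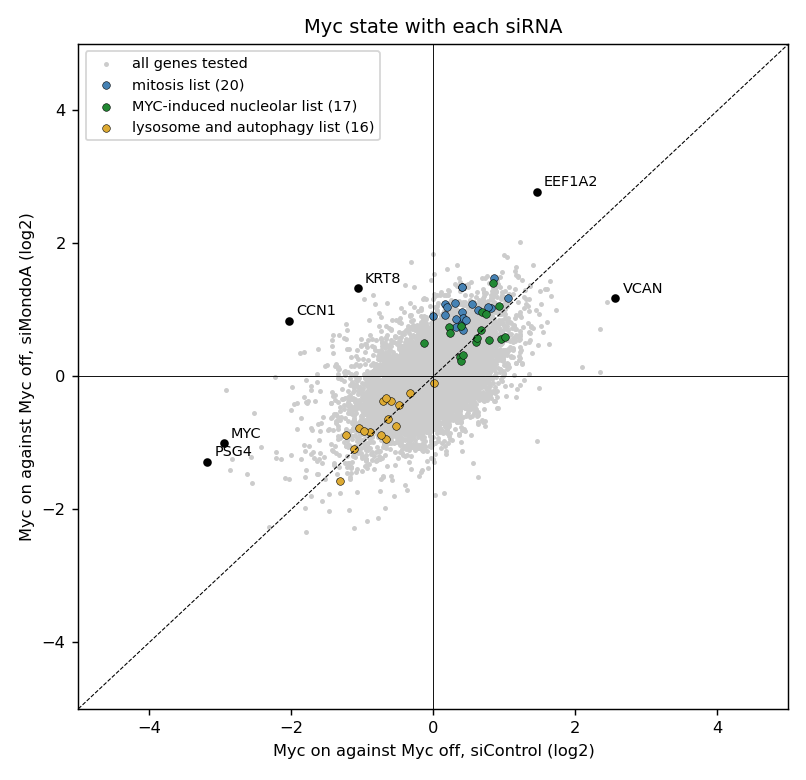
Log2 change of every tested gene between Myc on and Myc off with siControl (horizontal axis) and with siMondoA (vertical axis), each dot a gene, with the 20 mitosis, 17 nucleolar and 16 lysosome and autophagy genes coloured and a dashed line where both changes are equal. All 20 mitosis genes passed as higher with siMondoA and 11 with siControl, and MYC lies at -2.95 and -1.0.

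The interaction compared the knockdown change with Myc on with that with Myc off, which is the design's test of whether the response to MondoA loss depends on Myc state. CCN1 had the largest value (2.87 ± 0.18, adjusted p = 7.5e-06), having changed by -1.58 on the log2 scale with Myc on and by -4.45 with Myc off. CRISPLD2 (2.71 ± 0.15), the growth factor gene HBEGF (2.23 ± 0.18) and the deiodinase gene DIO2 (2.22 ± 0.18) changed by 0.40, -0.10 and 0.21 with Myc on and by -2.31, -2.33 and -2.00 with Myc off. The keratin gene KRT8 (2.39 ± 0.19) and HKDC1, a hexokinase domain gene (2.19 ± 0.19), changed by 0.72 and 1.18 with Myc on and by -1.66 and -1.01 with Myc off. At the other end were FAM107B (-2.42 ± 0.19), the ubiquitin-like ligase gene HERC5 (-2.14 ± 0.16), CNTNAP2 (-1.95 ± 0.19), PGF (-1.90 ± 0.31) and ENHO (-1.86 ± 0.18), whose knockdown changes with Myc off were 2.08, 2.23, 2.00, 3.03 and 1.17. FAM107B was below the lowest detected signal on siControl Myc-off replicate 3 (4.841 against 5.109). ENHO was below it on siMondoA Myc-on replicate 2 (5.017 against 5.163). TMEM119 passed too but was above background in the siControl, Myc-on group alone, so its interaction has no measured size. MYC had an interaction of 1.95 ± 0.19 (adjusted p = 7.7e-05), and TXNIP of 1.07 ± 0.16 (adjusted p = 0.0022), its decrease being the larger with Myc off.

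Of the lists, 7 of 23 passed for the interaction. The mitosis list had a median of 0.55 with 7 of 20 members higher, 0 lower and 13 not passing (12 adjusted over the list alone, adjusted p = 2e-07), with BUB1 at 0.94 ± 0.16 and the cyclin CCNA2 at 0.92 ± 0.17. The p53 list had a median of -0.63 with 4 of 13 lower, 0 higher and 9 not passing (7 adjusted over the list alone, adjusted p = 4e-04), with SESN1 at -0.97 ± 0.16 and CDKN1A at -0.79 ± 0.13, another CDKN1A probe being at -2.10. The matrix list had a median of 0.35 with 4 of 21 higher, 0 lower and 17 not passing (6 adjusted over the list alone, adjusted p = 4e-04), with CCN2 at 2.04 ± 0.15. The mesenchymal list had a median of 0.36 with 3 of 14 higher, 0 lower and 11 not passing (6 adjusted over the list alone, adjusted p = 0.0016), namely SPARC (1.41 ± 0.22), THY1 (0.79 ± 0.15) and VIM, which encodes vimentin (0.77 ± 0.15). These 4 calls held with an estimated correlation (adjusted p = 0.0081, 0.032, 0.038 and 0.038). Oxidative phosphorylation had a median of -0.22 with 6 of 50 lower, 2 higher and 42 not passing (7 and 2 adjusted over the list alone, adjusted p = 4e-04, but adjusted p = 0.054 with an estimated correlation), with SDHD at -1.02 ± 0.22 and COX5B at 0.72 ± 0.15. DNA replication had a median of 0.36 with 4 of 19 higher, 0 lower and 15 not passing (5 adjusted over the list alone, adjusted p = 0.013, but adjusted p = 0.074 with an estimated correlation), with RRM2 at 1.03 ± 0.15. Interferon genes had a median of -0.24 with 4 of 16 lower, 0 higher and 12 not passing, also adjusted over the list alone (adjusted p = 0.016, but adjusted p = 0.13 with an estimated correlation), with IFIH1, an RNA sensor, at -0.73 ± 0.17.

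In limma, 1059 genes (8.7%) passed for the interaction, 627 with a positive and 432 with a negative value. The knockdown change was larger in size with Myc off for 887 of them and with Myc on for 172. For 446 the estimated changes had opposite signs in the 2 states, whether or not each change passed. Only 62 were called in both states and in opposite directions. Positive values made up 59.2% of the calls and 94.1% under median scaling, which put the median of all genes at 0.27. That scaling ended the calls of the mesenchymal list (adjusted p = 0.052, range 8.3e-05 to 0.052 over its alternatives) and of the interferon list (0.055, median turned to 0.08), and the interferon call also ended with the authors' values or no background correction (0.056 for each, range 0.0096 to 0.056). Without siControl Myc-on replicate 2, siControl Myc-off replicate 3 or siMondoA Myc-off replicate 1 the count was 678, 686 or 694.

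The glycolysis, extended MYC network, BCL2 family, hypoxia and adrenergic lists and the markers of blood, endothelium and epithelium passed in 0 of the 5 comparisons. The glycolysis list of 19 tested genes had 2 higher and 3 lower with the knockdown when Myc was on (4 and 3 adjusted over the list alone, median 0.05, mean -0.01, adjusted p = 0.95) and 3 higher and 7 lower when Myc was off, also adjusted over the list alone (adjusted p = 0.54). Its glucose transporter genes SLC2A1 (-0.66 ± 0.11 and -0.98 ± 0.11) and SLC2A3 (-1.06 ± 0.11 and -0.78 ± 0.11) fell with the knockdown in both states. The MondoA and ChREBP target list, which passed only between Myc states with siMondoA, did not pass with the knockdown (adjusted p = 0.95 and 0.7). With Myc on 1 of 6 rose and 1, TXNIP, fell (3 and 1 adjusted over the list alone), its median and mean differing in sign (0.24 and -0.33). With Myc off HK2 rose (0.91 ± 0.13) and 2 fell, TXNIP and LDHA (3 and 2 adjusted over the list alone). The extended MYC network list (9 tested) had MYC as its only call with the knockdown when Myc was on (median -0.05, mean 0.10, adjusted p = 0.95), and the MYC antagonist gene MXD3 fell with Myc off (-1.41 ± 0.24). In the BCL2 family 2 of 12 rose with Myc on and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.58), with BAX at 0.42 ± 0.14 with Myc on and 1.03 ± 0.14 with Myc off. In the hypoxia list 2 of 11 fell and 0 rose with Myc on (3 and 1 adjusted over the list alone, adjusted p = 0.95), ADM being at -0.81 ± 0.11. Of the adrenergic neuroblastoma markers 5 of 14 were tested and CHGB, which encodes a chromogranin, rose with Myc on by at least 1.36-fold, not being above background in siControl (list adjusted p = 0.58). Of 12 markers of blood, endothelium and epithelium 5 were tested, and that list had adjusted p = 0.95 and 0.64 with the knockdown. Its member KRT8 rose by 0.72 ± 0.14 with the knockdown when Myc was on and fell by 1.66 ± 0.14 when Myc was off, and with Myc off LYZ was at least 1.59-fold higher and PECAM1 at least 1.09-fold lower, while EPCAM was at 0.48.

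Median and mean differed in sign for some lists, each in a comparison in which the list did not pass. With the knockdown when Myc was on these were the extended MYC network, MondoA and ChREBP target, glycolysis, serine and DNA replication lists. With Myc off they were the extended MYC network, BCL2 family, hypoxia, mesenchymal and lysosome lists. The others were p53 targets between Myc states with siControl, the ATF4 list with siMondoA, and the extended MYC network for the interaction.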

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

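The tests of explanations for the larger knockdown response with Myc off and for MYC, and the splits with the additive effects removed, were chosen only after the results were seen; the other split tests and the interaction itself were planned.

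The knockdown changed 1059 genes differently in the 2 Myc states by limma's interaction test. Differences were positive for CCN1 (2.87), CRISPLD2 (2.71), KRT8 (2.39), HBEGF (2.23), DIO2 (2.22), HKDC1 (2.19), MYC (1.95) and TXNIP (1.07). They were negative for FAM107B (-2.42), HERC5 (-2.14), CNTNAP2 (-1.95), PGF (-1.9) and ENHO (-1.86). FAM107B and ENHO each lay below the lowest detected signal on an array, as given above. TMEM119 also passed but was above background only in the siControl, Myc-on group, so its interaction has no measured size; with the knockdown it was at least 3.6-fold lower there. Of 239 other named genes 71 had an interaction, against 8.7% of all genes tested. Most of these were named for large changes in the same data, which raises their share. Lists with one were mitosis (median 0.55), DNA replication (0.36), mesenchymal markers (0.36), extracellular matrix (0.35), oxidative phosphorylation (-0.22), interferon response (-0.24) and p53 targets (-0.63). The DNA replication, oxidative phosphorylation and interferon calls were lost with an estimated correlation (adjusted p = 0.074, 0.054 and 0.13), and the interferon median turned to 0.08 under median scaling.

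The knockdown called more genes, and lowered TXNIP further, with Myc off than with Myc on. A deeper knockdown that moved the same genes further was not excluded, and MLXIP was not above background. The share against a deeper knockdown, opposite in sign or larger with Myc on, was 4.01% (95% interval 3.25 to 4.9) of the 2293 genes called in both states. It was 46.6% (43.6 to 49.7) of the 1059 called by the interaction, by estimated changes that need not each have passed. Each choice of genes leaned its own way. A smaller spread between the Myc-off arrays could not have raised their count, since all groups shared 1 estimate of the spread. The within-group SD of the Myc-off arrays was in any case 1.01 times that of the Myc-on arrays. The quantile normalization was excluded as the only cause of the larger changes. Under median scaling their SD with Myc off was 1.35 times that with Myc on (1.29 to 1.4 with an array left out). That scaling called 3285 genes with Myc on and 4521 with Myc off, against 3026 and 5333 with quantile normalization. Part of the excess in calls therefore depended on the normalization. A response that depends on Myc state or on doxycycline stays open as a hypothesis beside a deeper knockdown.

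MYC differed less between Myc states with siMondoA than with siControl. A Myc switch weakened as a whole was not seen in the nucleolar and nucleotide lists. They changed with siMondoA by 1 times their change with siControl (95% bootstrap interval 0.861 to 1.4, 36 genes), against 0.34 times for MYC. That interval resamples genes, which are not independent, and leaves out the spread between arrays. A weakened switch is not excluded, since the matrix list (median -0.69 with siControl and -0.29 with siMondoA) and the mesenchymal list (-0.44 and -0.16, the latter not passing camera, adjusted p = 0.18) differed less with siMondoA, as MYC did. A fault of the 1 MYC probe used was not excluded: with the other probe, not above background in siControl cells with Myc on and there raised to the detection floor, the interaction was at least 1.04 but did not pass (limma adjusted p = 0.083), although its changes went the same way, the knockdown raising it by at least 1.21 with Myc on (adjusted p = 0.0034) against 0.16 with Myc off (0.62). An effect of MondoA loss on the MYC transcript that depends on Myc state or doxycycline stays open as a hypothesis.

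Other splits of the 6 arrays of a pairwise comparison are too few (10) for a share under 0.05. In 1 of the 10 splits, the real one, each count of genes was as large: 3026 for the knockdown with Myc on, 5333 with Myc off, 3757 for Myc state with siControl and 3655 with siMondoA, the highest other split calling 0 genes in limma each time. The real splits had 4477, 6172, 4915 and 5008 genes at an unadjusted p under 0.05. For gene lists, 1 of 10 splits was as large for the knockdown with Myc on (5, highest other 0), 2 with Myc off (5, highest other 6), 1 for Myc state with siControl (12, highest other 11) and 1 with siMondoA (14, highest other 11). Of 100 splits for the interaction, 5 called as many genes, the highest other calling 5781 against 1059, so chance was not excluded by that count. Such splits exchange most siRNA labels within 1 Myc state and so point to a structure of the samples, the knockdown's own change entering the interaction. With the additive effects removed, 1 of 100 was as large (1059, highest other 1), which excludes a chance split of these arrays. It does not exclude chance between cultures, since the replicates may be technical. The 7 lists of the interaction were matched by 1 of 100 splits, the real one (highest other 6). Those splits kept the additive effects, and the lists were not split again without them, so chance was not excluded for the lists. For the 2231 genes called in the same direction by both knockdown comparisons (1 of 100, highest other 62) and the 1816 called by both Myc-state comparisons (1 of 100, highest other 132) the splits decide nothing, since splits that mix the groups of a comparison called 0 genes in it, as given above, whether or not genes are shared.

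Probes without a single gene symbol also differed between groups: of 5803 tested, limma called 400 for the knockdown with Myc on, 1140 with Myc off, 436 for Myc state with siControl, 431 with siMondoA and 49 for the interaction.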

How the results depend on the processing

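Median scaling of the gene lists and all alternatives for the gene families were added after the data were seen; the others were planned. A slide block was not run, since no slide is given in the sources used here. The 4 pairwise counts stayed within 1.5 times under every alternative run except a 1.5-fold minimum, which leaves fewer genes by construction: 1598 and 3328 for the knockdown with Myc on and off, 2025 and 1962 for Myc state with siControl and siMondoA. With an array left out these counts were 2322 to 2472, 4571 to 5145, 2947 to 3178 and 2921 to 3373. A similar count did not mean the same genes. Of the knockdown calls, median scaling kept 2179 of 3026 with Myc on and 4176 of 5333 with Myc off. Of the Myc-state calls it kept 2701 of 3757 with siControl and 2550 of 3655 with siMondoA. Of the interaction calls it kept 700 of 1059. The interaction count was 1695 with the authors' values, 1698 without background correction and 678 to 1142 with an array left out, lowest without siControl Myc-on replicate 2 (678), siControl Myc-off replicate 3 (686) and siMondoA Myc-off replicate 1 (694); fewer arrays lower it by construction in part, and otherwise the cause was not tested. For the knockdown with Myc on, 3 lists passed under median scaling, 3 to 5 with an array left out (3 without siMondoA Myc-on replicate 1), 0 with an estimated correlation and 13 with fry; the cause was not tested for the first of these. With Myc off 3 passed with an estimated correlation and 17 with fry, for Myc state with siControl 22 with fry, and for the interaction 4 with an estimated correlation and 13 with fry, which asks another question than camera. At an adjusted p under 0.01, 1201 and 987 genes were shared in direction by the knockdown and the Myc-state comparisons, fewer by construction. With the mean of a gene's probes 3 named values turned in sign, because probes of the gene disagree: PCNA with the knockdown and Myc on (-0.009), PSPH with Myc off (0.012) and the interaction of INSIG1 (0.025). Of 417 named calls 52 were lost under median scaling, 18 with the mean of probes, 17 without a filter, 11 with the authors' values, 5 with the larger offset and 1 with array weights, and 11 to 31 of those compared when an array was left out. The replicate numbers share no deviations (18 same-number pairs, r of -0.097 to 0.083, 0 above 0.1; 3 of 12 arrays correlated best with their own number). With a replicate block the counts were 2881, 5240, 3647, 3500 and 904, the last for the interaction, and 5, 5, 12, 14 and 7 lists passed. Signal over background limits the genes tested: MLXIP, MYCN and ARRDC4 could not be compared.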

Other observations

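The gene families described here and all tests of explanations for them were chosen only after the results were seen.

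Replication-dependent histone genes rose with the MondoA siRNA in both Myc states. Of 38 tested, 28 rose and 0 fell with Myc on (median log2 change 1.3, camera adjusted p = 7.6e-21) and 31 rose and 0 fell with Myc off (median 1.2, adjusted p = 1e-13), with adjusted p = 0.0013 and 0.0058 with an estimated correlation. H2AC19 was at 2.79 ± 0.16 and 2.47 ± 0.16 (SE, n = 3 per group), and the linker histone gene H1-2 at 2.74 ± 0.16 and 2.39 ± 0.16. Under median scaling 29 rose in each state. With the authors' values, which have no background correction, 29 rose with Myc on and 30 with Myc off, and 0 fell. Their medians were then 0.51 and 0.5, so the size of the rise depended on the background correction and its direction did not. Which forms of the histone transcripts were carried into the cRNA and read by these probes was not tested. The probes for small nucleolar RNAs read higher with Myc on: of 131 genes tested, 66 rose and 1 fell with siControl (median 0.52, camera adjusted p = 2.4e-14, 0.00031 with an estimated correlation) and 75 rose and 2 fell with siMondoA (median 0.65, camera adjusted p = 5e-16, 2e-04 with an estimated correlation). With the knockdown 39 fell and 6 rose when Myc was on (median -0.25, adjusted p = 4.4e-05) and 52 fell and 11 rose when Myc was off (median -0.34, adjusted p = 0.00012). Their directions were the same under median scaling, where camera with the estimated correlation gave adjusted p = 0.054 and 0.069 for Myc state and 0.15 and 0.32 for the knockdown. With the authors' values their medians were 0.21 for Myc state with siControl and -0.088 and -0.13 for the knockdown with Myc on and off. Whether these probes read the mature small nucleolar RNAs or longer transcripts that contain them was not tested.

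Of 5 HLA class I genes, which present peptides, 4 fell and 0 rose with the knockdown when Myc was on (median -1.2, adjusted p = 2.2e-05, 0.0083 with an estimated correlation), with HLA-B at -1.52 ± 0.13 and HLA-F at -1.38 ± 0.13. With Myc off 3 fell and 0 rose (median -0.45, adjusted p = 0.015, but adjusted p = 0.077 with an estimated correlation). All 5 fell with Myc on against off in siControl cells (median -0.69, adjusted p = 0.00079) and 4 fell in siMondoA cells (median -1.1, adjusted p = 0.00047). Under median scaling the directions were the same, with adjusted p = 0.045 and 0.32 for the knockdown with Myc on and off and 0.17 and 0.069 for Myc state with an estimated correlation. Of 14 tubulin genes, 9 fell and 1 rose with the knockdown when Myc was off (median -0.45, adjusted p = 0.00067) and 3 rose and 3 fell when Myc was on, and the interaction passed (median 0.51, adjusted p = 8.7e-06, 0.0067 with an estimated correlation), with TUBB4B at 1.32 ± 0.16. Under median scaling the adjusted p with an estimated correlation was 0.32 for the tubulins with Myc off, against 0.014 without it, and 0.49 for their interaction, at a median of 0.67. Of 79 mitochondrial ribosomal protein genes 40 rose and 3 fell with the knockdown when Myc was off (median 0.35, adjusted p = 7.7e-06, but adjusted p = 0.077 with an estimated correlation). Between Myc states with siControl 38 rose and 1 fell (median 0.32, adjusted p = 1.7e-09, 0.033 with an estimated correlation), but under median scaling 11 rose and 1 fell (adjusted p = 0.31 with an estimated correlation). Their interaction median was -0.24 and turned to 0.092 under median scaling. Chemokines, cytosolic ribosomal proteins and keratins were also examined. With the preset correlation the cytosolic ribosomal proteins passed camera for the knockdown with Myc off (median 0.15, adjusted p = 0.015). They also passed for Myc state with siControl (median 0.15, adjusted p = 1e-04) and for the interaction (median -0.14, adjusted p = 0.0044). Chemokines passed for Myc state with siControl (median -0.35, adjusted p = 0.02), and keratins in no comparison. With an estimated correlation and the settings used throughout, none of these families passed in any comparison. The cytosolic ribosomal proteins did for Myc state with siControl with the authors' values (median 0.15, adjusted p = 0.035).

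For the rise of histone transcripts, more cells in S phase was examined as a cause. With Myc off the DNA replication list moved down on balance, against what that cause predicts (median -0.32, limma's fry, adjusted p = 1.7e-05). The list did not pass camera there (adjusted p = 0.052), and transcript levels do not count cells in S phase. That cause is therefore not excluded. With Myc on that list was at -0.04 (limma's fry, adjusted p = 0.83), its members going both ways, and S phase cannot be told apart there. One abundant histone transcript binding the probes of the others was excluded across families, since 5 families (H1, H2A, H2B, H3 and H4) had members called at least 2-fold higher in both states, 21 genes in all, while such binding within a family stays open. The quantile normalization was excluded, since 27 of the 38 genes were called higher in both states under median scaling, as many as without it. A change in histone transcript processing or stability with MondoA loss may remain as a hypothesis that no test here addressed, beside an effect of the siRNA on other transcripts.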
